A study of Mus musculus with 12 samples.

How the data were processed

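Total RNA of primary white adipocytes was sequenced as 12 libraries on an Illumina NovaSeq instrument, 4 for each of negative control, let-7d-5p mimic and let-7e-5p mimic, per the labels. The differentiation medium held IBMX at 250 µM, insulin at 850 nM and both dexamethasone and rosiglitazone at 1 µM. The mimics were delivered by reverse transfection, per the labels' protocols. The deposited count table holds whole-number counts per Ensembl gene, not normalized, with each library in its own column. STAR and the mouse build GRCm38.p6 are named in the submitters' processing notes, and the version, the read counter, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies cannot be told apart on this basis, so values of genes with such copies, Pgam1 and Eno1 of glycolysis among them, are uncertain. The authors removed genes with low CPM before they deposited the table, per its name, at an unstated threshold, and the lowest maximum CPM left in it is 0.456. A second deposited table, named RPKM, was checked against the counts and read as a score. The gene length its values imply differs between libraries for the same gene, by a median ratio of 64.7 between the highest and the lowest library, and repeats at a lag of 55487 places down the columns (correlation 0.9998), so it is not the RPKM of the gene each line names. It served only as an alternative.

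All 15754 genes of the count table were tested, because edgeR's filterByExpr removed none, and 15736 identifiers were matched to symbols of GENCODE vM21 (GRCm38.p6). Library sizes were scaled by TMM, and edgeR's quasi-likelihood test was fitted to all 12 libraries, which share 1 estimate of the spread, with a term for group and one for the run of sample identifiers (8 residual degrees of freedom). Adjusted p-values are those of edgeR after Benjamini and Hochberg over all genes, two-sided, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE), and CPM are given as mean and standard deviation (SD) over the 4 libraries of a group, both runs together. Nothing in the labels says that the replicates are separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The median SE was 0.085 on the log2 scale with let-7d and 0.084 with let-7e. The design text gives n = 6 where 4 libraries per group are listed, and these 4 are used. No pair of libraries of a group and run agreed within counting noise, with a chi-square per degree of freedom from 2.37 to 10.2.

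Before the data were examined, 33 gene lists, the tests, the rule for named genes and the alternatives were fixed, with exceptions given where they occur. The lists cover let-7 targets of the literature, the microRNA machinery, respiratory complexes I, II and III together, and IV, ATP synthase, messages of the mitochondrial genome, the tricarboxylic acid cycle, fatty acid oxidation, the mitochondrial ribosome, mitochondrial biogenesis and dynamics, mitochondrial protein folding and proteolysis, adipocyte identity, fat synthesis, lipolysis, thermogenic genes, insulin signalling, glycolysis, cholesterol synthesis, the cell cycle, extracellular matrix, preadipocytes, the interferon response, inflammatory cytokines, p53 targets, the ATF4 response, endoplasmic reticulum chaperones, antioxidant defence and markers of macrophages, endothelium, mesothelium, smooth muscle and lymphocytes. Lists with at least 5 measured members (32 of 33) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation and with fry, adjusted over lists within a comparison. Camera compares a list with all other genes, and fry asks whether its genes move on balance one way. The named genes were the 8 called genes with the largest rise and the 8 with the largest fall against control, among genes with an average log2 CPM of at least 2 in which every mimic library lay on one side of the control mean of its own run, leaving out predicted genes. From each called list came the 4 members with the smallest p, from each other list 2, between the mimics the 5 largest differences each way, and always Dicer1 and Hmga2. The text gives part of these genes, and names it where a gene falls outside the rule.

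Sites for let-7 were sought in the 3' UTR of the protein-coding transcript with the longest annotated 3' UTR, which 13547 tested genes have. The shift of genes with a site was tested with 100000 two-sided permutations of gene labels within 20 bins of 3' UTR length, and its interval came from 10000 bootstrap draws of genes at 95%. The coding sequence was searched likewise, and the mimics' complements beyond the seed in both. Neither p nor interval holds the spread between libraries. Genes are not independent.

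The replicate numbers were checked for pairing. Deviations from the group means correlated at 0.832 to 0.881 between libraries with the same number (12 pairs), at 0.782 to 0.882 between different numbers of the same run (12 pairs) and at -0.891 to -0.805 across runs (24 pairs), and after removal of each run's group means at -0.065 to 0.188 for the same number. The numbers thus pair the libraries mainly through the run, which the model holds, and a fit with the replicate number as a block in place of the run is given where it changes a call. Other alternatives were DESeq2's size factors, DESeq2's Wald test, limma-voom, a filter of CPM 2 in 4 libraries, no further filter, no run term, only the 8 libraries compared, each run alone, each library left out in turn, and limma on the log2 of the second table with a pseudocount of 0.1 or 1.

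Data simulated from these libraries tested the scripts. Of 50 genes changed by 1.25, 1.5 and 3-fold with let-7d edgeR called 24%, 70% and 94%, and with let-7e 38%, 80% and 96%. Of 100 between the mimics it called 37%, 76% and 98%. Unchanged genes called were 7, 12 and 16. Camera found a simulated fall of -0.3 in glycolysis and 0 of 31 other lists, with either correlation. Simulated genes lacked correlation, so calls of correlated lists were not tested. Shifts of site genes of -0.1 and 0 with let-7d came back as -0.099 and -0.0014 (permutation p = 0.85 for 0). A difference between the runs of 1.5, 2, 3 and 4-fold with let-7d was called for 17, 28, 42 and 41 of 50 genes, and for 12 unchanged genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.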

Results

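RNA was sequenced from white adipocytes grown from the stromal vascular fraction of mouse epididymal fat, which is the non-fat-cell part of the tissue and holds fat cell precursors together with vascular and immune cells. The donors were male mice of the inbred C57BL/6 strain, 8 weeks old and fed chow. The cultures were turned into fat cells with rosiglitazone, insulin, dexamethasone and IBMX, transfected on day 4 with a synthetic mimic of let-7d-5p, a mimic of let-7e-5p or a negative control, and harvested on day 7. MicroRNAs of the let-7 family guide Argonaute proteins to messages that pair with them, which are then degraded or translated less. The series is about let-7 and mitochondrial dysfunction, so the comparisons ask which messages change when fat cells receive either microRNA, those of mitochondrial proteins among them. Each group had 4 libraries, and 15754 genes had counts. The total per library ran from 15071299 counts in control replicate 2 to 33396316 in let-7e replicate 3, and 15703 to 15742 genes had a count above 0.

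The 12 libraries fell into 2 series of sample identifiers, called ID run 1 (replicates 1 and 2 of each group) and ID run 2 (replicates 3 and 4). The labels do not say what sets the runs apart. The first principal component held 81.9% of the variance and separated the runs, and the second held 4.57%. Scd1, the desaturase that makes monounsaturated fatty acids, had the highest count in every library of ID run 1 and took 1.93% to 2.34% of all counts there. In ID run 2 the highest count was that of Eef1a1, a translation elongation factor, with 0.978% to 1.05%. Adipocyte identity genes, macrophage markers and interferon response genes differed in level between the runs, as the plot of list levels shows. Both runs held 2 libraries of each group, so every comparison was fitted with a run term and values within each run are given for called lists, and for other lists where a run gave a call.

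**Figure D1:**
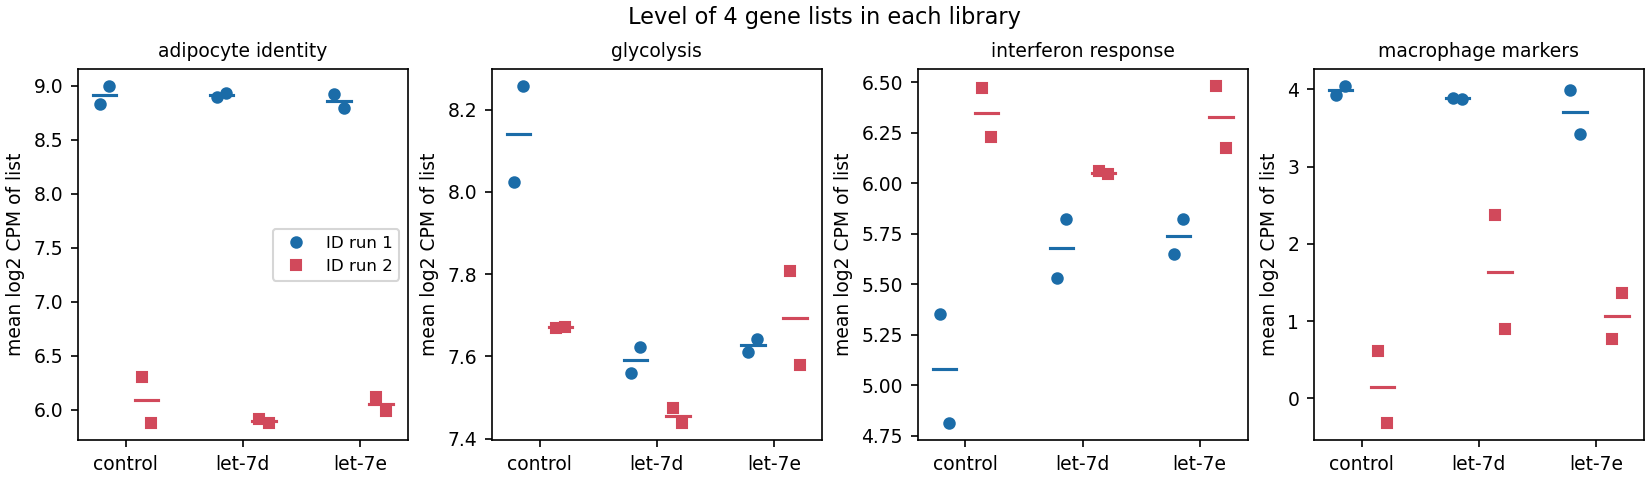
Mean log2 CPM (counts scaled to a common library size) of 4 gene lists in each library (points, 12 libraries) with the mean of each group and ID run (bars). Adipocyte identity genes lay at 8.80 or more in ID run 1 and between 5.87 and 6.30 in ID run 2, and macrophage markers in ID run 2 ranged from -0.32 in control replicate 4 to 2.38 in let-7d replicate 3.

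The let-7d mimic was compared with the negative control to ask what this microRNA does to fat cell messages. Among the largest changes, the proteases Mmp3 and Mmp13 and the chemokine Cxcl5 rose, while Megf10, H19, Acta1 and Col8a2 fell. Mmp3, the matrix protease stromelysin 1 (chromosome 9, 7445822 to 7455975, GRCm38), went from 32.3 ± 19.5 CPM in the controls to 82.4 ± 45.8 CPM (SD, n = 4 each), a log2 fold change of 1.36 ± 0.11 (SE) with an edgeR adjusted p of 4.60e-06. Within the runs its mean went from 16.5 to 44.2 CPM in ID run 1 and from 48.2 to 121 CPM in ID run 2. Mmp13, a collagenase, rose by 1.54 ± 0.23, Cxcl5, a chemokine that attracts neutrophils, by 1.74 ± 0.29, and Chl1, a cell adhesion molecule, by 1.77 ± 0.27. Among the genes that fell were Megf10, an engulfment receptor (-1.46 ± 0.15), the imprinted noncoding RNA H19 (-1.44 ± 0.16), skeletal muscle actin Acta1 (-1.44 ± 0.18), the collagen gene Col8a2 (-1.29 ± 0.11), Pappa, a protease of insulin-like growth factor binding proteins (-1.21 ± 0.12), and Aspn, a small matrix proteoglycan (-1.12 ± 0.14). Mrps12, a protein of the mitochondrial ribosome, rose by 0.80 ± 0.066. Each of these genes passed the edgeR test, with adjusted p up to 0.000736 (Cxcl5), and lay on the same side of its run's control mean in all 4 let-7d libraries.

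Known targets of let-7 from the literature fell as a group with the let-7d mimic. Of this list 22 fell of 49 tested, and 1 rose and 25 fell adjusted over the list alone. These targets had a median log2 fold change of -0.16, -0.14 in ID run 1 and -0.17 in ID run 2 (camera adjusted p = 1.27e-07, or 0.0413 with an estimated correlation). Dicer1, the enzyme that cuts microRNA precursors, fell by 0.52 ± 0.061 (SE, edgeR adjusted p = 4.84e-05). It went from 52.5 ± 14.3 to 36.4 ± 8.92 CPM (SD, n = 4 each), with -0.55 in ID run 1 and -0.47 in ID run 2. The gene lies on chromosome 12 at 104687742 to 104751952 (GRCm38, minus strand). Hmga2, a chromatin protein of embryonic and growing tissue on chromosome 10 (120361275 to 120476469, minus strand), fell from 20.0 ± 7.34 to 11.3 ± 4.92 CPM (log2 fold change -0.84 ± 0.098, edgeR adjusted p = 4.73e-05, -0.95 in ID run 1 and -0.73 in ID run 2). The growth signalling genes Nras (-0.47 ± 0.047) and Igf1r (-0.30 ± 0.058) and the transcriptional repressor E2f6 (-0.60 ± 0.066) fell as well, with edgeR adjusted p of 1.44e-05, 0.00202 and 3.15e-05. The fixed list of the microRNA machinery shares Dicer1, Lin28b and Trim71 with this one. It stood at 1 up and 4 down of 20, 1 and 5 adjusted over the list alone, camera adjusted p = 0.286. Ago2, the Argonaute protein that can cut its target, stood at -0.44 ± 0.071 (SE, edgeR adjusted p = 0.000546).

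Messages for sugar, cholesterol and fat metabolism were lower with the let-7d mimic. In glycolysis 14 fell of 18 tested, and 1 rose and 16 fell adjusted over the list alone. Glycolysis had a median log2 fold change of -0.37, -0.55 in ID run 1 and -0.18 in ID run 2 (camera adjusted p = 3.72e-06, or 0.735 with an estimated correlation). The genes that fell included the kinases Hk2 (-0.58 ± 0.080) and Pfkp (-0.43 ± 0.057), the mutase Pgam1 (-0.62 ± 0.094) and the enolase Eno1 (-0.51 ± 0.099). In cholesterol synthesis 1 rose and 14 fell of 24 tested, and 3 rose and 16 fell adjusted over the list alone. Cholesterol synthesis had a median log2 fold change of -0.22, -0.13 in ID run 1 and -0.27 in ID run 2 (camera adjusted p = 0.000170, or 0.735 with an estimated correlation). The sterol enzyme Mvd changed by -0.40 ± 0.068, while the sterol carrier Stard4 rose by 0.33 ± 0.055. In fatty acid oxidation 8 fell of 23 tested, and 1 rose and 10 fell adjusted over the list alone. Fatty acid oxidation had a median log2 fold change of -0.14, -0.12 in ID run 1 and -0.14 in ID run 2 (camera adjusted p = 0.000506, or 0.735 with an estimated correlation). Etfdh, which passes electrons from fatty acids to the respiratory chain, stood at -0.36 ± 0.060. In fat synthesis 1 rose and 7 fell of 20 tested, and 1 rose and 10 fell adjusted over the list alone. Fat synthesis had a median log2 fold change of -0.15, -0.017 in ID run 1 and -0.23 in ID run 2 (camera adjusted p = 0.00272, or 0.735 with an estimated correlation). Among them were fatty acid synthase Fasn (-0.49 ± 0.094) and the acyltransferase Agpat2 (-0.41 ± 0.078). The fat synthesis list was called in ID run 2 (camera adjusted p = 0.000258) and not in ID run 1 (0.185). The camera calls of these lists held in all 8 fits that left out 1 of the 8 libraries compared.

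Matrix, contractile and stress lists also fell with the let-7d mimic. Of the extracellular matrix genes 3 rose and 16 fell of 38 tested, and 3 rose and 17 fell adjusted over the list alone. Matrix genes had a median log2 fold change of -0.17, -0.26 in ID run 1 and -0.032 in ID run 2 (camera adjusted p = 5.72e-05, or 0.735 with an estimated correlation). Col6a3 stood at -0.95 ± 0.082, Col8a1 at -0.66 ± 0.055, the crosslinking enzyme Loxl2 at -0.54 ± 0.051 and the membrane protease Mmp14 at -0.56 ± 0.059. Smooth muscle and pericyte markers, which name another cell type of the fat tissue, moved with them. Of these 4 fell of 14 tested, and 1 rose and 8 fell adjusted over the list alone. Smooth muscle markers had a median log2 fold change of -0.22, -0.30 in ID run 1 and -0.096 in ID run 2 (camera adjusted p = 0.0236, or 0.735 with an estimated correlation). Acta2 stood at -0.34 ± 0.077, Myh11 at -0.35 ± 0.073 and Actg2 at -0.47 ± 0.088. Among p53 targets 1 rose and 9 fell of 20 tested, and 2 rose and 11 fell adjusted over the list alone. The p53 list had a median log2 fold change of -0.15, -0.16 in ID run 1 and -0.14 in ID run 2 (camera adjusted p = 0.00613, or 0.735 with an estimated correlation). Plk2 stood at -0.56 ± 0.070, Btg2 at -0.47 ± 0.067, Zmat3 at -0.37 ± 0.052 and, rising, Trp53inp1 at 0.72 ± 0.092. Of the genes of the ATF4 stress response 6 fell of 23 tested, and 7 fell adjusted over the list alone. ATF4 response genes had a median log2 fold change of -0.15, -0.19 in ID run 1 and -0.10 in ID run 2 (camera adjusted p = 0.00260, or 0.735 with an estimated correlation). Asparagine synthetase Asns stood at -0.26 ± 0.057 and the mitochondrial folate enzyme Aldh1l2 at -0.43 ± 0.081. In ID run 2 alone the smooth muscle, p53 and ATF4 lists were not called (camera adjusted p = 0.209, 0.112 and 0.0595).

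Macrophage markers were called higher with let-7d, and lipolysis, thermogenic, insulin signalling and some mitochondrial lists were lower. Of the macrophage markers 4 rose of 18 tested, and 4 rose adjusted over the list alone. Macrophage markers had a median log2 fold change of 0.33, -0.0072 in ID run 1 and 1.91 in ID run 2 (camera adjusted p = 0.00579, or 0.785 with an estimated correlation). The list was called in ID run 2 (camera adjusted p = 1.53e-06) and not in ID run 1 (0.419). Without let-7d replicate 3 the median of both runs was 0.0096, and without control replicate 4 it was 0.18. Lyz2, the lysozyme of myeloid cells, changed by 1.10 ± 0.34 (edgeR adjusted p = 0.0374, 0.22 in ID run 1 and 2.26 in ID run 2) and the lysosomal protein Cd68 by 0.69 ± 0.22 (edgeR adjusted p = 0.0457, 0.29 in ID run 1 and 1.46 in ID run 2). The edgeR adjusted p of Lyz2 became 0.105 without control replicate 3, 0.113 without control replicate 4 and 0.0952 without let-7d replicate 3, and 0.0523 with the replicate number as a block. That of Cd68 became 0.0708 without control replicate 1, 0.0623 without let-7d replicate 1, 0.0826 without control replicate 3, 0.0927 without control replicate 4 and 0.105 without let-7d replicate 3. Without let-7d replicate 3 the log2 fold change was 0.65 ± 0.24 for Lyz2 and 0.44 ± 0.17 for Cd68. In lipolysis and lipid droplets 5 fell of 20 tested, and 1 rose and 9 fell adjusted over the list alone. Lipolysis genes had a median log2 fold change of -0.18, -0.12 in ID run 1 and -0.35 in ID run 2 (camera adjusted p = 0.0251, or 0.785 with an estimated correlation). The hormone-sensitive lipase Lipe stood at -0.52 ± 0.11 and the droplet protein Fitm2 at -0.37 ± 0.070. Of the thermogenic genes 8 fell of 17 tested, and 1 rose and 8 fell adjusted over the list alone. Thermogenic genes had a median log2 fold change of -0.28, -0.23 in ID run 1 and -0.26 in ID run 2 (camera adjusted p = 0.0311, or 0.735 with an estimated correlation). The potassium channel Kcnk3 stood at -0.65 ± 0.11 and the elongase Elovl3 at -0.99 ± 0.18. In insulin signalling 1 rose and 6 fell of 24 tested, and 1 rose and 7 fell adjusted over the list alone. Insulin signalling had a median log2 fold change of -0.096, -0.0018 in ID run 1 and -0.16 in ID run 2 (camera adjusted p = 0.0256, or 0.785 with an estimated correlation). The receptor substrate Irs1 stood at -0.41 ± 0.097. In respiratory complex IV 5 fell of 14 tested, and 5 fell adjusted over the list alone. Complex IV genes had a median log2 fold change of -0.11, -0.19 in ID run 1 and 0.010 in ID run 2 (camera adjusted p = 0.0403, or 0.785 with an estimated correlation). They were led by the muscle and brown fat subunits Cox8b (-0.93 ± 0.15) and Cox7a1 (-0.51 ± 0.12), which the thermogenic list also holds. In the tricarboxylic acid cycle and pyruvate entry 4 fell of 21 tested, and 6 fell adjusted over the list alone. The cycle had a median log2 fold change of -0.071, -0.029 in ID run 1 and -0.049 in ID run 2 (camera adjusted p = 0.0470, or 0.828 with an estimated correlation). Pyruvate carboxylase Pcx stood at -0.84 ± 0.11 and isocitrate dehydrogenase Idh2 at -0.29 ± 0.059. In respiratory complexes II and III 2 fell of 14 tested, and 2 fell adjusted over the list alone. These complexes had a median log2 fold change of -0.096, -0.11 in ID run 1 and -0.055 in ID run 2 (camera adjusted p = 0.0494, or 0.819 with an estimated correlation). The called genes were Uqcrc1 (-0.26 ± 0.058) and Cycs (-0.29 ± 0.062). In ID run 1 alone lipolysis, insulin signalling and the cycle were not called (camera adjusted p = 0.267, 0.437 and 0.419), nor in ID run 2 alone complex IV (0.583) and complexes II and III (0.496). Single libraries decided these 7 list calls, and without control replicate 2 camera called 10 lists in place of 16. Without 1 library the camera adjusted p of the macrophage list became 0.0905 (control replicate 4) and 0.150 (let-7d replicate 3), and of lipolysis 0.131 and 0.0910 (control replicates 2 and 3). For the thermogenic list it became 0.0776 and 0.0547 (control replicates 2 and 4), and for insulin signalling 0.150, 0.0682 and 0.150 (control replicates 2 and 4, let-7d replicate 3, medians -0.069, -0.069 and -0.044). That of complex IV became 0.120, 0.150, 0.0905, 0.0914 and 0.0557 (control replicates 1, 2 and 3, let-7d replicates 1 and 4). For the cycle it was 0.279, 0.152, 0.0566, 0.0904 and 0.0884 (control replicates 2 and 3, let-7d replicates 1, 3 and 4). For complexes II and III it ran from 0.0535 to 0.279 (control replicates 1, 2 and 3, let-7d replicates 1, 3 and 4). Without control replicate 2 the medians were -0.049 for complex IV, -0.026 for the cycle (-0.047 and -0.045 without control or let-7d replicate 3) and -0.058 for complexes II and III. Among calls that stayed, medians were smaller for smooth muscle without control replicate 1 (-0.13), fatty acid oxidation without control replicate 2 (-0.087) and p53 targets without control replicate 4 (-0.094) or let-7d replicate 3 (-0.092).

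Other mitochondrial lists did not pass the camera test with let-7d. For respiratory complex I the count was 1 up and 2 down of 36, 1 and 2 adjusted over the list alone, camera adjusted p = 0.155. The mitochondrial ribosome stood at 2 up and 2 down of 76, 1 and 1 adjusted over the list alone, camera adjusted p = 0.966. Mitochondrial biogenesis and dynamics stood at 0 up and 3 down of 27, 0 and 3 adjusted over the list alone, camera adjusted p = 0.973. Mitochondrial protein folding and proteolysis stood at 0 up and 1 down of 10, 0 and 1 adjusted over the list alone, camera adjusted p = 0.606. For ATP synthase (16 genes) and the messages of the mitochondrial genome (7 genes) edgeR, DESeq2 and limma-voom called 0 genes, with 4 and 0 at an unadjusted edgeR p under 0.05, and the camera adjusted p was 0.321 and 0.923. Adipocyte identity stood at 1 up and 3 down of 24, 1 and 3 adjusted over the list alone, camera adjusted p = 0.223. The cell cycle stood at 2 up and 3 down of 38, 2 and 3 adjusted over the list alone, camera adjusted p = 0.826. Antioxidant defence stood at 6 up and 1 down of 22, 6 and 3 adjusted over the list alone, camera adjusted p = 0.675. Preadipocyte and fibroblast markers stood at 4 up and 1 down of 14, 7 and 2 adjusted over the list alone, camera adjusted p = 0.224, with the precursor receptor Pdgfra at 0.31 ± 0.052. Endoplasmic reticulum chaperones stood at 3 up and 1 down of 17, 3 and 1 adjusted over the list alone, camera adjusted p = 0.150. Inflammatory cytokines and NF-kB targets stood at 6 up and 2 down of 21, 7 and 3 adjusted over the list alone, camera adjusted p = 0.0871, or 0.0431 with the replicate number as a block. The secreted pentraxin Ptx3 stood at 0.60 ± 0.064 and the cytokine signalling inhibitor Socs3 at 0.38 ± 0.056. Interferon response genes had medians of opposite sign in the runs, 0.47 in ID run 1 (camera adjusted p = 5.71e-07) and -0.28 in ID run 2 (3.05e-06), at the preset correlation. Pooled they were not called (camera adjusted p = 0.108, or 0.828 with an estimated correlation), and 0 of 36 passed in edgeR, DESeq2 or limma-voom, with 2 at an unadjusted edgeR p under 0.05. Endothelial markers stood at 0 up and 1 down of 16, 0 and 1 adjusted over the list alone, camera adjusted p = 0.155, with the VEGF receptor Flt1 at -0.49 ± 0.057. Mesothelial markers stood at 0 of 15 in all 3 tools, 1 at an unadjusted edgeR p under 0.05, camera adjusted p = 0.826. Of the lymphocyte markers 1 gene was measured, the cytokine receptor Il7r, at 0.44 ± 0.32 with let-7d (edgeR adjusted p = 0.392, 0.046 in ID run 1 and 1.64 in ID run 2, 0.10 to 0.67 with 1 library left out) and 0.35 ± 0.31 with let-7e (0.575, 0.18 in ID run 1 and 1.07 in ID run 2, 0.12 to 0.52). The cell cycle also had medians of opposite sign, 0.14 in ID run 1 (camera adjusted p = 0.0182) and -0.085 in ID run 2 (0.0257), with an adjusted p of 0.982 pooled with an estimated correlation. In 1 run alone camera called complex I (-0.11, adjusted p = 0.00108) and the chaperones (0.083, 0.0160) in ID run 1, and adipocyte identity (-0.22, 0.0170) and endothelial markers (0.38, 0.0224) in ID run 2. Some lists gained a camera call when 1 library was left out. Without control replicate 4 the camera adjusted p was 0.000652 for complex I and 0.0422 for adipocyte identity, and without let-7d replicate 2 it was 0.0152 for endothelial markers. Without let-7d replicate 4 it was 0.0439 for the chaperones and 0.0336 for inflammatory and interferon genes. The interferon list also had 0.00182, 0.0452 and 0.0344 (control replicates 3 and 4, let-7d replicate 3). The median, the mean and the camera direction differed in sign for the mitochondrial ribosome, mitochondrial biogenesis, antioxidant and mesothelial lists.

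**Figure D2:**
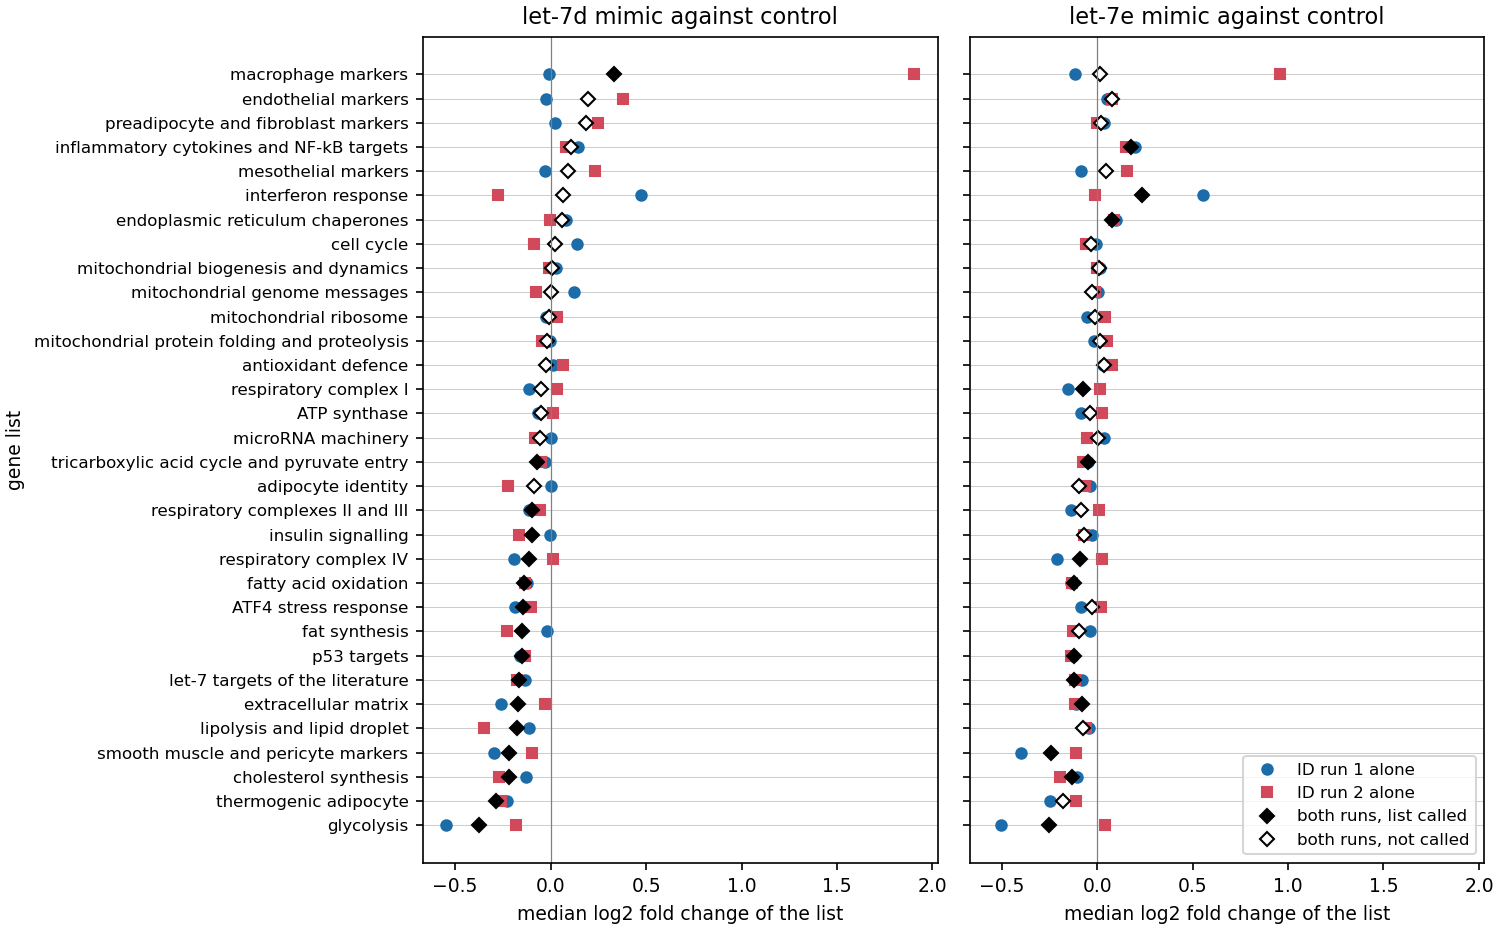
Median log2 fold change of 32 gene lists with each mimic, in ID run 1 (circles), ID run 2 (squares) and both runs together (diamonds, filled where camera called the list). Glycolysis with let-7d lay at -0.55 and -0.18 in the runs.

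By edgeR 2555 of the 15754 genes differed between let-7d and control (16.2%), 1010 higher and 1545 lower. Their median size was 0.32 on the log2 scale, and 210 rose and 205 fell by over 1.5-fold. In 2504 of the 2555 all 4 let-7d libraries lay on one side of their run's control mean. ID run 1 alone gave 2149 genes and ID run 2 alone 740, and without the run term 7 genes were called, with 830 at an unadjusted p under 0.05. Camera called 16 of 32 lists. With only these 8 libraries in the fit the count was 15, and 6 of their 34 splits called at least as many. With an estimated correlation only the let-7 targets stayed called.

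The let-7e mimic was compared with the same controls to ask the same question of the second microRNA. Among the largest changes, Mmp3, Mmp13 and the chemokines Cxcl5 and Cxcl9 rose, while Acta1, H19, Col8a2 and Eln fell. Mmp3 rose by 1.17 ± 0.11 (SE, edgeR adjusted p = 1.64e-05) to 72.0 ± 39.0 CPM (SD, n = 4). Cxcl9, a chemokine that attracts T cells, rose from 4.46 ± 3.80 to 12.8 ± 10.4 CPM. Chl1 rose by 1.46 ± 0.27, Cxcl5 by 1.40 ± 0.29 and Mmp13 by 1.23 ± 0.23. Acta1 changed by -1.33 ± 0.18, H19 by -1.28 ± 0.15, the growth factor gene Ptn by -1.27 ± 0.14, Itih4, a protein of the inter-alpha-trypsin inhibitor family, by -1.16 ± 0.10, Col8a2 by -1.11 ± 0.11 and the elastin gene Eln by -1.06 ± 0.20. Mrps12 rose by 0.73 ± 0.065. These genes passed the edgeR test with adjusted p up to 0.00846 (Cxcl9), and each lay on the same side of its run's control mean in all 4 let-7e libraries. The basement membrane collagen gene Col4a2 stood at -0.99 ± 0.079 (SE, edgeR adjusted p = 6.57e-06).

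Of the known let-7 targets 13 fell of 49 tested, and 1 rose and 19 fell adjusted over the list alone with the let-7e mimic. These targets had a median log2 fold change of -0.12, -0.077 in ID run 1 and -0.12 in ID run 2 (camera adjusted p = 0.000124, or 0.200 with an estimated correlation). Dicer1 went to 38.4 ± 10.9 CPM (SD, n = 4; log2 fold change -0.45 ± 0.061, edgeR adjusted p = 0.000213, -0.42 in ID run 1 and -0.48 in ID run 2). Hmga2 went to 13.5 ± 5.94 CPM (log2 fold change -0.59 ± 0.095, edgeR adjusted p = 0.00105, -0.73 in ID run 1 and -0.47 in ID run 2). Nras changed by -0.40 ± 0.047 and E2f6 by -0.55 ± 0.065. Interferon response genes rose as a list. Of these 4 rose of 36 tested, and 5 rose adjusted over the list alone. Interferon genes had a median log2 fold change of 0.24, 0.55 in ID run 1 and -0.013 in ID run 2 (camera adjusted p = 7.07e-05, or 0.802 with an estimated correlation). That rise was in ID run 1 (camera adjusted p = 2.38e-10) and not in ID run 2 (0.736). Dhx58, a sensor of viral RNA, changed by 0.54 ± 0.13 (edgeR adjusted p = 0.0182, 0.87 in ID run 1 and 0.29 in ID run 2) and Trim30a by 0.53 ± 0.16 (edgeR adjusted p = 0.0461, 1.04 in ID run 1 and 0.14 in ID run 2). The edgeR adjusted p of Dhx58 became 0.0734 without control replicate 1, 0.0544 without let-7e replicate 1, 0.0541 without let-7e replicate 2 and 0.0610 without let-7e replicate 3, and that of Trim30a became 0.160 without control replicate 1, 0.119 without control replicate 2, 0.106 without let-7e replicate 1, 0.137 without let-7e replicate 2 and 0.0936 without let-7e replicate 3, and 0.0601 with the replicate number as a block. Of the inflammatory cytokines and NF-kB targets 7 rose and 1 fell of 21 tested, and 8 rose and 2 fell adjusted over the list alone. Inflammatory genes had a median log2 fold change of 0.18, 0.20 in ID run 1 and 0.15 in ID run 2 (camera adjusted p = 0.0165, or 0.723 with an estimated correlation). Ptx3 stood at 0.66 ± 0.064 and Socs3 at 0.32 ± 0.056. Of the endoplasmic reticulum chaperones 3 rose of 17 tested, and 3 rose adjusted over the list alone. Chaperones had a median log2 fold change of 0.078, 0.099 in ID run 1 and 0.091 in ID run 2 (camera adjusted p = 0.0165, or 0.802 with an estimated correlation). Sdf2l1, a part of a chaperone complex, stood at 0.35 ± 0.076. Both of these list calls were lost without let-7e replicate 3, with a camera adjusted p of 0.0804 for the inflammatory list and 0.111 for the chaperones (median 0.039). In ID run 1 alone neither was called (0.0662 and 0.0656).

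Metabolic, matrix and contractile lists fell with the let-7e mimic. In fatty acid oxidation 7 fell of 23 tested, and 9 fell adjusted over the list alone. Fatty acid oxidation had a median log2 fold change of -0.12, -0.14 in ID run 1 and -0.13 in ID run 2 (camera adjusted p = 0.000255, or 0.723 with an estimated correlation). Etfdh stood at -0.39 ± 0.060. In glycolysis 4 fell of 18 tested, and 9 fell adjusted over the list alone. Glycolysis had a median log2 fold change of -0.25, -0.50 in ID run 1 and 0.041 in ID run 2 (camera adjusted p = 0.000292, or 0.802 with an estimated correlation). Pgam1 stood at -0.42 ± 0.093 and Pfkp at -0.33 ± 0.056. The glycolysis list was called in ID run 1 (camera adjusted p = 3.92e-10) and not in ID run 2 (0.714). In cholesterol synthesis 2 rose and 7 fell of 24 tested, and 2 rose and 10 fell adjusted over the list alone. Cholesterol synthesis had a median log2 fold change of -0.13, -0.11 in ID run 1 and -0.19 in ID run 2 (camera adjusted p = 0.00428, or 0.802 with an estimated correlation). Mvd stood at -0.36 ± 0.067 and, rising, Insig1, which holds back sterol synthesis, at 0.40 ± 0.074 and Stard4 at 0.33 ± 0.054. Without control replicate 3 the cholesterol list had a camera adjusted p of 0.0551, and in ID run 1 alone 0.150. Of the smooth muscle and pericyte markers 5 fell of 14 tested, and 8 fell adjusted over the list alone. Smooth muscle markers had a median log2 fold change of -0.24, -0.40 in ID run 1 and -0.11 in ID run 2 (camera adjusted p = 0.000260, or 0.634 with an estimated correlation). Actg2 stood at -0.60 ± 0.088, Myh11 at -0.51 ± 0.073 and Acta2 at -0.36 ± 0.077. Of the extracellular matrix genes 3 rose and 15 fell of 38 tested, and 4 rose and 16 fell adjusted over the list alone. Matrix genes had a median log2 fold change of -0.078, -0.11 in ID run 1 and -0.12 in ID run 2 (camera adjusted p = 0.00409, or 0.723 with an estimated correlation). Col6a3 stood at -0.77 ± 0.082. Among p53 targets 2 rose and 6 fell of 20 tested, and 2 rose and 8 fell adjusted over the list alone. The p53 list had a median log2 fold change of -0.12, -0.13 in ID run 1 and -0.14 in ID run 2 (camera adjusted p = 0.00409, or 0.723 with an estimated correlation). Btg2 stood at -0.49 ± 0.066, the cell cycle inhibitor Cdkn1a at -0.32 ± 0.060 and, rising, Gadd45a at 0.33 ± 0.064. In ID run 2 alone the camera adjusted p was 0.0534.

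Respiratory complexes I and IV and the tricarboxylic acid cycle were called lower with let-7e, by small amounts. In complex IV 3 fell of 14 tested, and 5 fell adjusted over the list alone. Complex IV genes had a median log2 fold change of -0.089, -0.21 in ID run 1 and 0.028 in ID run 2 (camera adjusted p = 0.00878, or 0.802 with an estimated correlation). The list was called in ID run 1 (camera adjusted p = 1.65e-05) and not in ID run 2 (0.906). Cox8b stood at -0.99 ± 0.14, and Cox7a1 at -0.47 ± 0.12 (edgeR adjusted p = 0.0230) with opposite signs in the runs, -0.69 in ID run 1 and 0.087 in ID run 2. The adjusted p of Cox7a1 became 0.0778 without control replicate 1, 0.0997 without control replicate 2, 0.140 without let-7e replicate 1 and 0.138 without let-7e replicate 2. In complex I 2 rose and 2 fell of 36 tested, and 2 rose and 2 fell adjusted over the list alone. Complex I genes had a median log2 fold change of -0.072, -0.15 in ID run 1 and 0.016 in ID run 2 (camera adjusted p = 0.0221, or 0.937 with an estimated correlation). A call was made in ID run 1 (camera adjusted p = 2.31e-06) and not in ID run 2 (0.456). The subunit gene Ndufa6 rose by 0.27 ± 0.055. In the tricarboxylic acid cycle and pyruvate entry 2 fell of 21 tested, and 3 fell adjusted over the list alone. The cycle had a median log2 fold change of -0.048, -0.046 in ID run 1 and -0.073 in ID run 2 (camera adjusted p = 0.0433, or 0.937 with an estimated correlation). Pcx stood at -0.56 ± 0.11 and Idh2 at -0.38 ± 0.059. With the replicate number as a block the camera adjusted p of the cycle was 0.0556, and in ID runs 1 and 2 alone 0.106 and 0.113. Without 1 library the camera adjusted p of complex I became 0.0648, 0.395, 0.108, 0.0628, 0.170 and 0.0806 (control replicates 1, 2 and 3, let-7e replicates 1, 2 and 4). That of the cycle became 0.131 or more (control replicates 2 and 3, let-7e replicates 2 and 4), and of complex IV 0.0544 (let-7e replicate 2). Medians without control replicate 2 were -0.041 for complex I, -0.019 for the cycle and -0.053 for complex IV, and without let-7e replicate 2 -0.018 for the cycle and -0.059 for complex IV. Other calls stayed with smaller medians for smooth muscle without control replicate 1 (-0.13), glycolysis and interferon response without control replicate 2 (-0.12 and 0.11), let-7 targets without control replicate 4 (-0.076) and the inflammatory list without let-7e replicate 1 (0.10).

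The remaining lists did not pass the camera test with let-7e. Fat synthesis stood at 1 up and 2 down of 20, 2 and 7 adjusted over the list alone, camera adjusted p = 0.150, with Thrsp, a regulator of fat synthesis, at -0.97 ± 0.18 and the acyltransferase Gpam at 0.29 ± 0.060. Thermogenic genes stood at 0 up and 4 down of 17, 0 and 6 adjusted over the list alone, camera adjusted p = 0.0755. Lipolysis stood at 0 up and 1 down of 20, 0 and 0 adjusted over the list alone, camera adjusted p = 0.632. Insulin signalling stood at 1 up and 2 down of 24, 2 and 3 adjusted over the list alone, camera adjusted p = 0.360. Adipocyte identity genes stood at 1 up and 0 down of 24, 1 and 0 adjusted over the list alone, camera adjusted p = 0.711. The ATF4 stress response stood at 1 up and 2 down of 23, 1 and 2 adjusted over the list alone, camera adjusted p = 0.470. Antioxidant defence stood at 5 up and 1 down of 22, 5 and 2 adjusted over the list alone, camera adjusted p = 0.143. The cell cycle stood at 1 up and 3 down of 38, 1 and 3 adjusted over the list alone, camera adjusted p = 0.470. Preadipocyte and fibroblast markers stood at 3 up and 1 down of 14, 3 and 2 adjusted over the list alone, camera adjusted p = 0.711. The microRNA machinery stood at 1 up and 3 down of 20, 1 and 3 adjusted over the list alone, camera adjusted p = 0.711. The mitochondrial ribosome stood at 1 up and 1 down of 76, 1 and 0 adjusted over the list alone, camera adjusted p = 0.711. Mitochondrial biogenesis and dynamics stood at 0 up and 1 down of 27, 0 and 1 adjusted over the list alone, camera adjusted p = 0.923. ATP synthase stood at 0 up and 1 down of 16, 0 and 1 adjusted over the list alone, camera adjusted p = 0.233. Endothelial markers stood at 0 up and 1 down of 16, 0 and 1 adjusted over the list alone, camera adjusted p = 0.512. EdgeR called 0 genes of the macrophage markers (18 tested, 1 at an unadjusted p under 0.05), mesothelial markers (15 and 1), messages of the mitochondrial genome (7 and 0), mitochondrial protein folding and proteolysis (10 and 2) and complexes II and III (14 and 3). The camera adjusted p of these 5 lists was 0.162, 0.870, 0.846, 0.883 and 0.0983. DESeq2 called 2 genes of complexes II and III and 0 of the other lists, and limma-voom called 0 in all 5. In 1 run alone camera called ATP synthase (-0.082, adjusted p = 0.0144), complexes II and III (-0.14, 0.00412) and the mitochondrial ribosome (-0.054, 0.0298) in ID run 1. In ID run 2 it called macrophage markers (0.96, adjusted p = 0.000230), antioxidant defence (0.076, 0.0353) and thermogenic genes (-0.11, 0.0438). Leaving out control replicate 1 gave a camera adjusted p of 0.0163 for fat synthesis and insulin signalling, 0.0177 for thermogenic genes, 0.0397 for macrophage markers and 0.0476 for antioxidant defence. Without control replicate 2 it was 0.0241 for the cell cycle and 0.0288 for macrophage markers, and without let-7e replicate 2 it was 0.0335 for the latter. Without control replicate 4 and let-7e replicate 3 it was 0.0281 and 0.0237 for ATP synthase and 0.00821 and 0.00665 for complexes II and III. Thermogenic genes had 0.0246 without let-7e replicate 3. The median, the mean and the camera direction differed in sign for the microRNA machinery, mitochondrial biogenesis and mesothelial lists.

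By edgeR 1496 genes differed between let-7e and control (9.50%), 600 higher and 896 lower. Of these 97 rose and 159 fell by over 1.5-fold, and all 4 let-7e libraries lay on one side of their run's control mean in 1471. ID run 1 alone gave 1540 genes and ID run 2 alone 197. Without the run term edgeR called 0 genes, with 552 at an unadjusted p under 0.05, and without let-7e replicate 1 or 2 the count was 844 or 874. Camera called 13 lists. With only these 8 libraries in the fit the count was 12, and 12 of their 34 splits called at least as many. With an estimated correlation 0 lists stayed called, while fry called 4.

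The mimics were compared with each other to ask which messages respond differently to these members of one microRNA family. Few genes differed. P2rx4, an ATP-gated ion channel (chromosome 5, 122707544 to 122729738), was higher with let-7d than with let-7e by 1.20 ± 0.053 (SE, edgeR adjusted p = 2.38e-09), with 1.21 in ID run 1 and 1.20 in ID run 2. It stood at 49.2 ± 4.42 CPM with let-7d, 21.4 ± 1.73 with let-7e and 43.8 ± 6.58 in the controls (SD, n = 4 each). Col4a2 (chromosome 8, 11312805 to 11449287) was higher with let-7d by 0.61 ± 0.079 (edgeR adjusted p = 0.00473, 0.56 in ID run 1 and 0.67 in ID run 2), at 1232 ± 509 against 819 ± 363 CPM and 1693 ± 908 in the controls. Inpp5k, an inositol phosphatase of the insulin pathway, was higher by 0.55 ± 0.066 (edgeR adjusted p = 0.00211), at 23.0 ± 1.17 against 15.7 ± 1.52 CPM and 18.8 ± 0.769 in the controls. Derl3 (0.81 ± 0.14), a protein of endoplasmic reticulum quality control, and Odf2 (0.37 ± 0.064), a centrosome protein, were also higher. Apba1, a neuronal adaptor protein on chromosome 19 (23758887 to 23949596), was lower with let-7d by -0.67 ± 0.12 (edgeR adjusted p = 0.0443, -0.92 in ID run 1 and -0.40 in ID run 2), at 6.54 ± 0.964 against 10.8 ± 3.37 CPM and 9.55 ± 2.85 in the controls. The lipid scavenger receptor gene Olr1 (-0.53 ± 0.095), the semaphorin receptor gene Plxna4 (-0.52 ± 0.089), Enpp1, which makes pyrophosphate (-0.50 ± 0.092), and the lysyl oxidase Loxl3 (-0.49 ± 0.084) were lower too. With the replicate number as a block the edgeR adjusted p was 0.0599 for Derl3, 0.0599 for Odf2, 0.0590 for Apba1, 0.0628 for Olr1, 0.0590 for Plxna4, 0.0599 for Enpp1 and 0.0600 for Loxl3, so none of these 7 kept its call.

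These genes were also read against the control, chosen because the direct comparison named them. With let-7d P2rx4 stood at 0.18 ± 0.051 (edgeR adjusted p = 0.0269), which became 0.0625 without let-7d replicate 2, 0.0640 without control replicate 3, 0.0764 without control replicate 4, 0.0814 without let-7d replicate 3 and 0.0511 without let-7d replicate 4. With let-7e it fell by 1.02 ± 0.053 (SE, edgeR adjusted p = 3.13e-08, -1.10 in ID run 1 and -0.93 in ID run 2). Col4a2 stood at -0.38 ± 0.079 with let-7d (edgeR adjusted p = 0.00361) and -0.99 ± 0.079 with let-7e, and Inpp5k at 0.30 ± 0.066 and -0.26 ± 0.067 (edgeR adjusted p = 0.00582 and 0.0241). The adjusted p of Inpp5k with let-7e became 0.0515 without control replicate 1, 0.0779 without control replicate 2, 0.0792 without let-7e replicate 1, 0.0809 without let-7e replicate 2 and 0.0627 without let-7e replicate 3. Apba1 stood at -0.50 ± 0.13 with let-7d (edgeR adjusted p = 0.0137, and 0.0518 without control replicate 2 and 0.0524 without let-7d replicate 1) and 0.17 ± 0.12 with let-7e, which did not pass (edgeR adjusted p = 0.453).

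**Figure D3:**
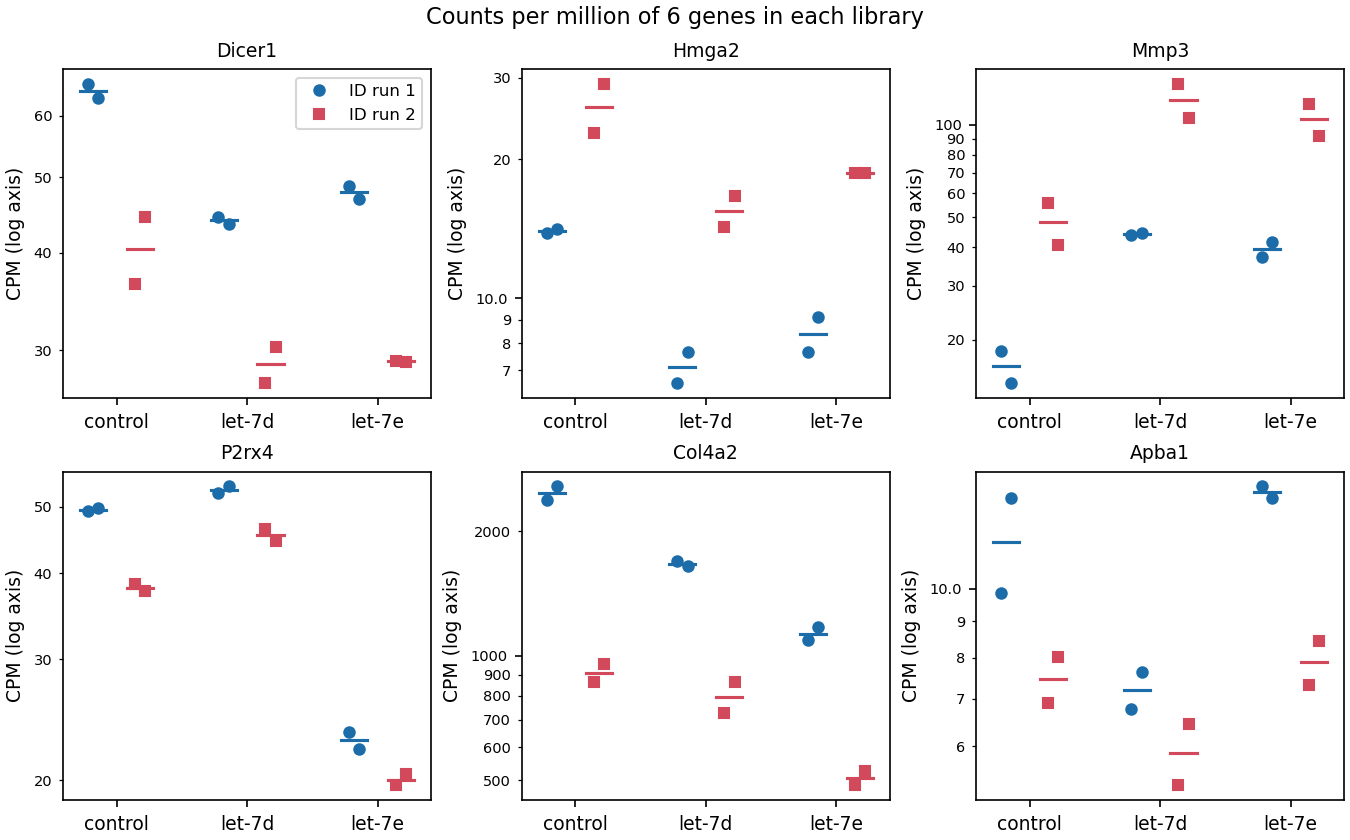
CPM, on a log axis, of 6 genes in each library (points, 12 libraries) with the mean of each group and ID run (bars). P2rx4 had a mean of 21.4 CPM with let-7e against 43.8 in the controls and 49.2 with let-7d, and Apba1 a mean of 6.54 CPM with let-7d against 9.55 and 10.8.

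By edgeR 24 genes differed between the mimics, 9 higher and 15 lower with let-7d, and all but P2rx4, Col4a2 and Inpp5k lost the call in at least 1 fit that left out a library. The count was 3 without let-7d replicate 1, 2 or 4 or let-7e replicate 2 or 3, 4 without let-7e replicate 1, 7 without let-7d replicate 3 and 17 without let-7e replicate 4. It was 5 with the replicate number as a block, 2 in ID run 1 alone and 1 in ID run 2 alone, and DESeq2 called 122 and limma-voom 20.

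Camera called 10 lists between the mimics, with medians from -0.20 to 0.38. With medians in ID runs 1 and 2 after each p, lower with let-7d were the let-7 targets (median -0.062, camera adjusted p = 0.000653, or 0.312 with an estimated correlation; -0.057 and -0.072), the ATF4 stress response (-0.11, 0.000653; -0.082 and -0.091), interferon response (-0.20, 0.00152; -0.083 and -0.27), fat synthesis (-0.11, 0.00249; -0.036 and -0.19) and glycolysis (-0.14, 0.00259; -0.039 and -0.22). So were extracellular matrix (-0.088, 0.00259; -0.16 and -0.015), lipolysis (-0.12, 0.00268; -0.011 and -0.19), cholesterol synthesis (-0.074, 0.00494; -0.084 and -0.083) and insulin signalling (-0.038, 0.0141; -0.016 and -0.084). Macrophage markers were called higher (median 0.38, camera adjusted p = 0.0107; 0.14 and 0.87), but without let-7d replicate 3 the median was 0.025 and camera placed the list lower. With an estimated correlation the last 9 of these had an adjusted p = 0.906. Of their genes edgeR called 1 of the ATF4 list, Asns (-0.32 ± 0.057, named after its value was seen, edgeR adjusted p = 0.0599 with the replicate number as a block), lower, and 1 of the extracellular matrix, Col4a2, higher, and adjusted over the list alone 1 rose and 7 fell of the matrix list and 1 each fell of the ATF4 list, lipolysis and glycolysis. In the other 8 lists edgeR called 0 genes, with 11 of the let-7 targets at an unadjusted p under 0.05 and 0 to 6 in the rest, while DESeq2 called 1 in lipolysis and 1 in glycolysis and limma-voom 0. Without let-7d replicate 3 the count of lists was 6. Of these 10 lists only the let-7 targets and the ATF4 list were called in both runs alone. Endothelial markers, not called pooled, were called in both with opposite medians, -0.099 in ID run 1 (camera adjusted p = 0.0177) and 0.28 in ID run 2 (0.0107), and pooled had an adjusted p of 0.922 with an estimated correlation. In 1 run alone camera called the cell cycle (0.098, adjusted p = 5.05e-05) in ID run 1, and adipocyte identity (-0.10, 0.00298), chaperones (-0.084, 0.0270) and preadipocyte markers (0.19, 0.00615) in ID run 2. The calls were lost without let-7d replicate 3 for cholesterol, fat synthesis, insulin signalling and macrophage markers (camera adjusted p = 0.438, 0.149, 0.539 and 0.994), with medians of -0.025, -0.070 and -0.0014 for the first 3. They were also lost without let-7d replicate 1 for the matrix (0.0524), without let-7d replicate 4 for interferon (0.0532), without let-7e replicate 2 for macrophages (0.171, median 0.20), without let-7e replicate 3 for glycolysis (0.181, median -0.062) and without let-7e replicate 4 for insulin signalling (0.101). At least 11 lists, the count with only these 8 libraries in the fit, were called by 14 of their 34 splits. The other 22 lists were not called, with camera adjusted p from 0.0954 to 0.905. Of these the cell cycle gained a call without let-7d replicate 4 (camera adjusted p = 5.55e-05) or let-7e replicate 3 (0.0112). The latter library's omission also gave calls to the mitochondrial ribosome (0.00463) and complex I (0.00357). Calls came for preadipocytes without let-7d replicate 1 (0.0335) or let-7e replicate 1 (0.0351), endothelium without let-7d replicate 2 (0.0131), adipocyte identity without let-7e replicate 2 (0.0372) and smooth muscle without let-7e replicate 4 (0.0253). The inflammatory, mitochondrial ribosome and mitochondrial biogenesis lists had a median and a mean of different sign.

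Both responses were compared over all genes. Across 15754 genes, which are not independent replicates, the fold changes had Pearson's r = 0.758 and Spearman's rho = 0.738. Shared controls alone gave r = 0.516 (0.494 to 0.544) in 50 simulations of unchanged groups. Simulated genes lacked correlation, so simulated ranges and counts may be too small. The covariance was 0.0576 against a simulated 0.0150 (0.0138 to 0.0163), a difference of 0.0426. With the controls split so that each mimic had its own pair of libraries, r lay between 0.386 and 0.468 and the covariance between 0.0379 and 0.0436. Both mimics raised 432 genes and lowered 731, where independent lists of these sizes share 38.5 and 87.9 and unchanged groups gave 0 and 0.02. With the controls split the shared genes averaged 160.5 risen (127 to 177) and 297.5 fallen (248 to 337). Opposite calls were made for 2 genes, P2rx4 and Inpp5k.

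**Figure D4:**
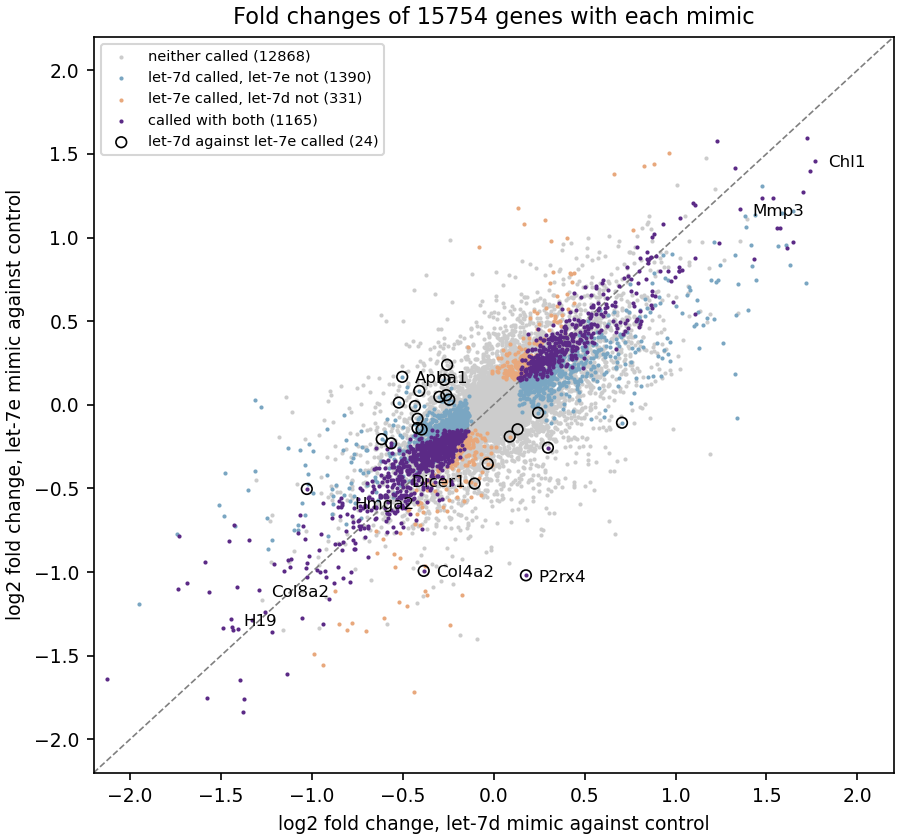
Log2 fold change of each of 15754 genes with the let-7d mimic (x axis) and the let-7e mimic (y axis) against the same controls, coloured by which edgeR test called it, with the 24 genes called between the mimics ringed and 4 genes outside the axes. P2rx4 lay at 0.18 and -1.02, and Mmp3 at 1.36 and 1.17.

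Genes with sites for let-7 were compared with genes without, to ask whether messages that can pair with the microRNA fell. Both mimics, AGAGGUAGUAGGUUGCAUAGUU (let-7d) and UGAGGUAGGAGGUUGUAUAGUU (let-7e), share the seed GAGGUAG, whose 8-base site in a message reads CTACCTCA. Of the 13547 genes with an annotated 3' UTR 508 held this site there, and 11246 held no 7-base or 8-base site. Genes with the 8-base site were lower than those without by a mean of -0.11 (SE 0.012, 95% interval -0.137 to -0.0902) with let-7d, -0.10 in ID run 1 and -0.12 in ID run 2. With let-7e the shift was -0.083 (SE 0.010, -0.103 to -0.0628), -0.068 in ID run 1 and -0.10 in ID run 2. After the part expected from 3' UTR length the shifts were -0.095 and -0.079. The two-sided permutation p was 1e-05 for both, the smallest that 100000 permutations can give, across genes, which are not independent replicates. Mean log2 fold changes with let-7d were -0.095 for the 8-base site, -0.075 for CTACCTC alone (919 genes), -0.068 for TACCTCA alone (874 genes) and 0.019 for no site, and with let-7e -0.077, -0.073, -0.050 and 0.0060. With let-7d 24.4% of genes with the 8-base site fell by the edgeR test and 3.54% rose, against 8.65% and 7.43% of genes with no site, and with let-7e 15.7% and 2.76% against 4.78% and 4.53%.

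Single sites were located in the named genes on GRCm38. Hmga2 holds the 8-base site in its 3' UTR, in exon 6 of 6 on chromosome 10 at 120364224 to 120364231, and E2f6 in exon 7 of 7 on chromosome 12 at 16826418 to 16826425. Igf1r holds it in its 3' UTR in exon 21 of 21 on chromosome 7 at 68229125 to 68229132. Dicer1 holds no such site in its 3' UTR and 3 in its coding sequence, in exon 21 of 27 at 104702804 to 104702811 and 104702696 to 104702703 and in exon 24 of 27 at 104694696 to 104694703. The 3' UTRs of Ago2, Pappa, Olr1 and Thrsp hold the 8-base site, and those of Nras, Apba1 and Plxna4 hold CTACCTC without it. Those of Col4a2 and Acta1 hold TACCTCA alone, and those of Col6a3, Col8a2, Mmp3, Mrps12 and P2rx4 hold none of these. Over all genes with no site in the 3' UTR, 582 held the 8-base site in the coding sequence. They were lower than the 10664 without it by -0.10 (SE 0.012, 95% interval -0.126 to -0.0794) with let-7d and -0.091 (SE 0.010, -0.111 to -0.0714) with let-7e, or -0.083 with each mimic beyond the part expected from length, with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give.

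**Figure D5:**
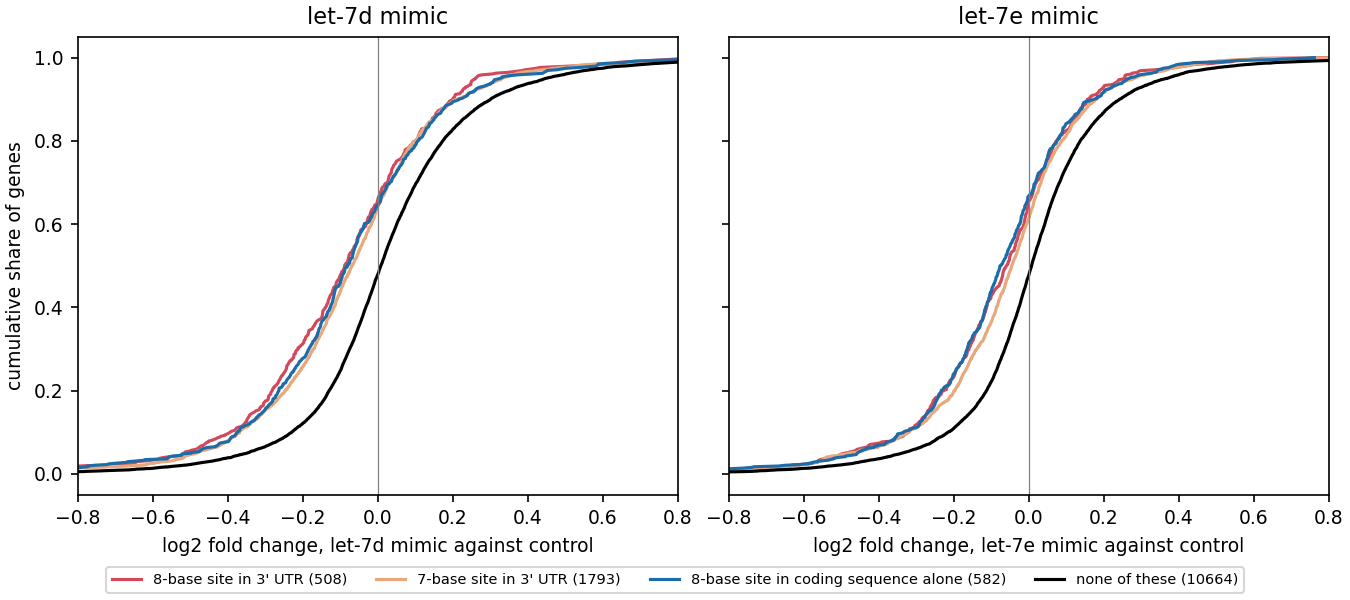
Cumulative share of genes (y axis) against log2 fold change with each mimic (x axis), for genes with the 8-base site in the 3' UTR (508), a 7-base site there (919 and 874), the 8-base site in the coding sequence alone (582) and none of these (10664). The mean with let-7d was -0.095 for the first of these and the curves of all 3 site classes lie to the left of genes without a site.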

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

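The counts over other splits of the libraries and the test of whole lists between runs were chosen after the results were seen.

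The let-7d fold change differed between the ID runs for 38 of 15754 genes by edgeR's interaction test (2136 at an unadjusted p under 0.05). Signed, it was higher in ID run 2 for 10 and lower for 28. Cebpb, a transcription factor of fat cell differentiation and inflammation, stood at 0.0047 in ID run 1 and 0.77 in ID run 2 (difference 0.76 ± 0.11, edgeR adjusted p = 0.0150). Npnt, a basement membrane protein, stood at 1.13 and 0.22 (difference -0.92 ± 0.11, adjusted p = 0.00631), Cilp, a matrix protein, at -1.24 and 0.00015 (1.23 ± 0.15, adjusted p = 0.00631) and the elongase Elovl3 at -0.66 and -2.05 (-1.40 ± 0.26, adjusted p = 0.0467). The interferon response genes Trim30a (0.92 and -0.042), Oas2 (0.64 and -0.28) and Gbp5 (1.28 and 0.046) were among those lower in ID run 2. Their edgeR adjusted p was 0.0479, 0.0479 and 0.0498. These genes were chosen after their values were seen.

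The count of 38 rested on few libraries: it was 219 without control replicate 1, 60 without control replicate 2, 20 without let-7d replicate 1, 0 without let-7d replicate 2 (1540 at an unadjusted edgeR p under 0.05), 5 without let-7d replicate 3 and 180 without let-7d replicate 4. With let-7e 1 gene differed between the runs by edgeR, the gene model Gm20559, at 0.83 in ID run 1 and -0.10 in ID run 2 (difference -0.92 ± 0.12, adjusted p = 0.0362), and 1398 genes had an unadjusted p under 0.05. That count was 153 without control replicate 1, 7 without control replicate 4, 17 without let-7e replicate 4, and 0 without control replicate 2 or 3 or let-7e replicate 1, 2 or 3, where 1552, 1679, 1002, 1017 and 1118 genes had an unadjusted edgeR p under 0.05. DESeq2 called 194 genes with let-7d and 52 with let-7e, and limma-voom 16 and 0 (1410 at an unadjusted p under 0.05 with let-7e).

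The 18 splits that keep the runs apart are too few for a share under 0.05. With only the 8 libraries compared in the fit, let-7d gave 18 genes, 2 of the 18 splits, the real one included, gave as many, and the highest other gave 2246. For let-7e the numbers were 2 genes, 3 of the 18 splits with the real one, and 1457. The split with 2246 and that with 1457 exchange mimic and control between the runs, so that the interaction holds the effect of the mimic itself.

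As whole lists, interferon response genes differed between the runs with both mimics, by a median of -0.78 with let-7d (camera adjusted p = 6.87e-15) and -0.55 with let-7e (2.44e-14), and so did macrophage markers (2.05 and 1.23, camera adjusted p = 8.58e-09 and 7.13e-07) and glycolysis (0.36 and 0.53, camera adjusted p = 1.10e-06 and 7.18e-15). With an estimated correlation none of these 6 calls held, with adjusted p of 0.711 or more.

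A library stood far from the others of its group for 2 of 342 sets of 4 values, a distance that chance gives in about 1 of 20 sets drawn from 1 distribution, which sets of libraries from both runs are not. Dhx58 had 38.5 CPM in let-7d replicate 2 against 29.5 to 30.8 CPM in the other let-7d libraries, a gap of 0.856 of the range. Loxl3 had 194 CPM in let-7e replicate 3 against 134 to 143 CPM, a gap of 0.853 of the range.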

How the results depend on the processing

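Each run alone was added for the gene lists after the data were seen; the other alternatives were planned. The counts of genes called with let-7d, let-7e and between the mimics stayed within 1.5 times of 2555, 1496 and 24 with DESeq2's size factors, limma-voom and the stricter filter. Without the run term they were 7, 0 and 1, with 830, 552 and 115 at an unadjusted edgeR p under 0.05. ID run 2 alone gave 740, 197 and 1, and ID run 1 alone 2 between the mimics. Between the mimics DESeq2's Wald test gave 122, the 8 libraries alone 98 and the fit with the replicate number as a block 5. Limma on the second table gave 0, 0 and 0 at either pseudocount, with 819, 747 and 753 at an unadjusted p under 0.05 at 0.1. With 1 library left out the counts ran from 1781 to 2535, 844 to 1456 and 3 to 17. The second table's values are not of the genes named, so its result weighs no call. Other causes were not tested. The low-count filter removed no gene, so omitting it tests nothing.

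The counts of lists, 16, 13 and 10, became 8, 8 and 4 without the run term, 1, 0 and 0 with an estimated correlation, 8, 4 and 0 with fry, and 6 between the mimics in ID run 1 alone. With 1 library left out they ran from 10 to 17, 10 to 17 and 6 to 12, and 9, 7 and 3 lists were called in every such fit. The site shifts kept their direction and call in every setting, from -0.126 to -0.0995 with let-7d and from -0.0953 to -0.0684 with let-7e when 1 library was left out. The correlation of the mimics was 0.464, 0.386, 0.468 and 0.421 with split controls. The genes that differed between the runs, 38 and 1, became 194 and 52 with DESeq2 and 16 and 0 with limma-voom, and ran from 0 to 219 and from 0 to 153 with 1 library left out.

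The named genes gave 944 values with 1 library left out, of which 851 kept their direction and call and 93 kept the direction alone, and 1180 values in the other settings, of which 975 kept both, 204 the direction alone and 1 reversed. That was Cox7a1 with let-7e, at 0.087 in ID run 2 alone, and the cause was not tested. The block for the replicate number ended the calls of Lyz2 with let-7d, Trim30a with let-7e, and Derl3, Odf2, Apba1, Olr1, Plxna4, Enpp1, Loxl3 and Asns between the mimics, gave inflammatory cytokines a call with let-7d (camera adjusted p = 0.0431), ended that of the tricarboxylic acid cycle with let-7e (0.0556), and changed no other call of a named gene, or of a list against control. At this depth and spread many small changes are missed, since 24% to 38% of the smallest simulated changes were called. The effect of depth was not tested.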

Other observations

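The test of 7-mers ranked by shift over error, the counts over other splits, the comparison of the runs with each other and the base 12 limit of pairing were chosen after the results were seen.

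The ID runs differed in how far the cultures looked like fat cells. Adipocyte identity genes were lower in ID run 2 for 24 of 24 tested (median -3.26, camera adjusted p = 6.35e-10, adjusted p = 0.446 with an estimated correlation) and fat synthesis genes for 20 of 20 (-3.21, camera adjusted p = 2.08e-09, 0.446). Fasn was lower by -4.78 ± 0.089, the lipid droplet protein Plin1 by -3.45 ± 0.076, Scd1 by -3.69 ± 0.077, the hormone gene Adipoq by -1.86 ± 0.085 and the receptor Pparg by -1.57 ± 0.078 (SE, 6 libraries per run, edgeR). Fatty acid oxidation was lower for 22 of 23 genes (median -1.62, camera adjusted p = 8.95e-08, adjusted p = 0.446 with an estimated correlation), the tricarboxylic acid cycle for 21 of 21 (-1.13, 1.64e-07, 0.531) and macrophage markers for 17 of 18 (-2.84, 0.000250, 0.700), with Cd68 at -2.58 ± 0.18 and Lyz2 at -2.10 ± 0.28. Higher in ID run 2 were 18 of 23 genes of the ATF4 stress response (median 0.66, camera adjusted p = 0.000214, adjusted p = 0.677 with an estimated correlation), 15 of 20 p53 targets (0.68, 0.00399, 0.597), with Cdkn1a at 0.62 ± 0.049, 25 of 36 interferon response genes (0.77, 0.00516, 0.820) and 54 of 76 mitochondrial ribosome genes (0.31, 0.000502, 0.700). By edgeR 12864 genes (81.7%) differed between the runs. Across 14616 genes, which are not independent replicates, the fold changes of the mimic in ID run 1 and in ID run 2 had r = 0.334 with let-7d and 0.334 with let-7e.

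Genes with the 8-base let-7 site in the 3' UTR fell with both mimics. Base composition argues against itself as the cause: of 420 8-mers made of the same bases, CTACCTCA had the lowest shift with let-7d and rank 2 with let-7e, within bins of 3' UTR length. The test set before ranked CTACCTC at 24 (let-7d) and 17 (let-7e) among all 16384 7-mers by shift, where rank 10 was asked for, so it left pairing with the seed open. Ranked by shift over its error, CTACCTC and TACCTCA took rank 2 and 1 with let-7d and 1 and 2 with let-7e, which is consistent with pairing of the seed as a hypothesis found and tested on the same data. Of the 34 splits of the 8 libraries compared, 1, the real one, gave a shift of this size for each mimic (0.114 with let-7d against 0.101 in the highest other split, 0.0852 with let-7e against 0.0816). The splits cannot weigh chance, since many of them keep part of the real contrast. Of these splits 16 divide the libraries of each run 3 against 1, and the 18 that keep 2 against 2 are too few for a share under 0.05 (highest other 0.0741 with let-7d and 0.0606 with let-7e), as are the 8 of them that part every pair of replicate numbers (0.0741 and 0.0599).

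Genes with the 8-base site in the coding sequence and none in the 3' UTR were lower as well. The test asked for a fall in both mimics, and the weaker shift was -0.0913 (let-7e, 95% interval -0.111 to -0.0714). Base composition of the coding sequence is argued against, since among the 420 8-mers of the same bases the site ranked 1 with let-7e and 2 with let-7d, where 1 other 8-mer reached -0.0836 against -0.0827. Pairing inside coding sequences may thus lower messages about as 3' UTR sites do, as a hypothesis. Whether the affected messages differ in other ways was not tested.

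The mimics differ at bases 1, 9 and 16, and a few genes responded to one of them alone or in opposite ways. An effect of base 9 averaged over all seed sites of the 3' UTR is argued against as the cause: genes with C before every site (437) and with A (225) differed in the let-7d minus let-7e value by -0.0139, with a 95% upper bound of 0.0147 (two-sided permutation p = 0.327). Longer pairing with one mimic alone also rests on base 9 and is not covered by this. For pairing of bases 2 to 11 (CTCCTACCTC, 106 genes, against CTACTACCTC, 55 genes) the difference was 0.0603 with a permutation p of 0.136, which leaves it open. For pairing to base 12 or beyond, a limit set after P2rx4 and Apba1 were seen and tested without them, 38 genes paired with let-7e and 17 paired with let-7d differed by 0.138 (95% interval 0.0535 to 0.234, permutation p = 0.0116, 0.0348 adjusted over the 3 pairing tests). Longer pairing may account for part of the difference, as a hypothesis, but none of the 55 genes passed on its own by edgeR (smallest adjusted p 0.132 over them, 8 at an unadjusted p under 0.05) and most of the 24 genes called hold no such site.

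P2rx4 holds 1 stretch that pairs with let-7e to base 13, ACCTCCTACCTC, in its coding sequence (exon 7 of 12, chromosome 5, 122725015 to 122725026), as 4 genes in all do. Apba1 alone was found to pair with let-7d to base 14, at AACCTACTACCTC in its 3' UTR (exon 13 of 13, chromosome 19, 23948877 to 23948889).

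Other splits of the 8 libraries compared, 34 for each comparison with the run as a term, gave fewer genes than the real split: 0 at most against 1718 with let-7d, 2 against 1270 with let-7e and 53 against 98 between the mimics (1 of 34 each). The 18 that keep 2 libraries of each part in each run are too few for a share under 0.05, and the highest other among them gave 0, 2 and 0 genes. The split with 53 genes divides the runs 3 against 1. For the counts of lists chance stays open, and the splits cannot weigh it, since many keep part of the real contrast. With let-7d 6 of 34 splits gave at least the 15 lists of the real split (highest other 19). With let-7e 12 of 34 gave at least 12 (highest other 18), and between the mimics 14 of 34 at least 11 (highest other 20). The split with 19 lists sets control replicate 1 and let-7d replicates 1, 2 and 3 against the other libraries.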
